A study of Mus musculus with 16 samples.

How the data were processed

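Lungs of male mice were perfused with cold saline and frozen, RNA was taken from a frozen piece with TRIzol, and labelled single-stranded DNA made from 300 ng of total RNA was hybridised to Affymetrix arrays, per the labels' protocols. The deposited values are on a log2 scale, normalized by the authors by a method not given in the sources used here; that the scale is log2 was taken from the values. They were used as deposited. A normalization that equalises the arrays would remove a shift common to most genes. The table gives no detection calls, so signal over background was not assessed per probe set.

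Samples were assigned to groups by their labels, and the 16 arrays of the table were matched to samples by their labels. Of 41345 probe sets, 23521 had 1 gene symbol in the platform annotation, 1814 had several and 16010 were not listed there. Of the probe sets with 1 symbol, 23328 matched a current gene by Entrez ID, and 0 symbols changed. Only probe sets with 1 symbol were tested. For the 1082 genes with several such probe sets the one with the highest mean was taken. Genes with a mean under the 30th percentile (log2 5.626) were left out, and 15626 genes remained of 22180.

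Differences were tested with limma 3.58.1 in R 4.3.3, 2-sided, with a mean per group over all 16 arrays, contrasts, default eBayes and Benjamini-Hochberg adjustment within each of the 5 contrasts. These were ZT12 against ZT0 at each age, old against young at each time, and the interaction. A gene was called at an adjusted p under 0.05. The 39 gene lists and the rule for named genes were fixed before the data were examined. Of their 740 genes 608 were tested. The 37 lists with at least 3 tested genes were tested with limma's camera, with its preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with limma's fry. Named genes were, per contrast, the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap, leaving out symbols of predicted genes, clones and small RNAs, all tested clock genes, up to 4 members with the smallest adjusted p of each list described, and the cold-inducible genes. Which lists to describe was decided after the tests. Other called list members are named where they make up a count. A list median per array is the median, over its genes, of the distance from the gene's mean over all arrays.

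The fit was tested on simulated data for the 15626 genes, with 100 genes changed at each size. For the young time comparison 97% of genes changed by 1 on the log2 scale and 78% of those changed by 0.5 were recovered with 12 false calls. For the age comparison at ZT0 these were 97%, 77% and 5. In each simulation 1 list was called, the one that had been shifted. The simulated genes varied independently of each other, whereas the estimated correlation of the heat shock list in the data was 0.702. The simulation therefore does not show how often a list of correlated genes is called falsely.

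Alternatives were no filter or a stricter one (50th percentile), quantile normalization or median centring on top, eBayes with trend and robust settings, array weights, every probe set, the replicate number as a block, only the 8 arrays compared, and each array left out in turn. A cardiac marker covariate, leaving out the least correlated array of each group together, and age averaged over both times were added after the data were seen. For other splits of the arrays, all 35 splits were counted per comparison, and 100 relabelings of age within each time, the real one included, were taken for the interaction and the averaged age difference. Relabelings that only exchange the age names at a time were counted as the real one; this rule was set after a first run, in which such an exchange turned the interaction into the averaged age difference. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.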

Results

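The lungs of male C57BL/6J mice, an inbred laboratory strain, were profiled on Affymetrix whole-transcript arrays at 2 ages and at 2 times of day. Young mice were 2 months old and old mice 18 months old. Zeitgeber time 0 (ZT0) is lights on and ZT12 is lights off under a 12 h light and 12 h dark cycle. Each of the 4 groups had 4 arrays, which gives 16 arrays. Array medians over all probe sets lay between 6.249 and 6.302 on the log2 scale. The correlation of arrays within a group, across the 15626 genes tested, lay between 0.979 and 0.993. The number of arrays limits the precision of every value. The titles number the samples of a group from 1 to 4 without saying that each is a separate animal, so the p-values cover only the spread between these samples. All changes below are log2 differences with the standard error (SE) of the fit, with n = 4 arrays per group, over 15626 genes.

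The first comparison asked which lung transcripts differed between lights off and lights on in young mice. Dbp, a transcription factor driven directly by the clock, was 8.33-fold higher at ZT12 (log2 change 3.06, SE 0.14, adjusted p = 1.79e-09). Nr1d2 and Nr1d1, nuclear receptors that repress Arntl, were 5.27-fold and 4.73-fold higher, and Per3 was 3.81-fold higher. Arntl, which encodes the clock activator BMAL1, fell by 2.89 (SE 0.18), and Npas2, a relative of Clock, fell by 2.47 (SE 0.1). Spon2, a secreted matrix protein, fell by 2.66 (SE 0.14, adjusted p = 1.03e-08), and Adm, which encodes the vasodilator peptide adrenomedullin, fell by 1.65 (SE 0.13). Wee1, a kinase that holds cells before mitosis, rose by 1.13 (SE 0.12).

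**Figure D1:**
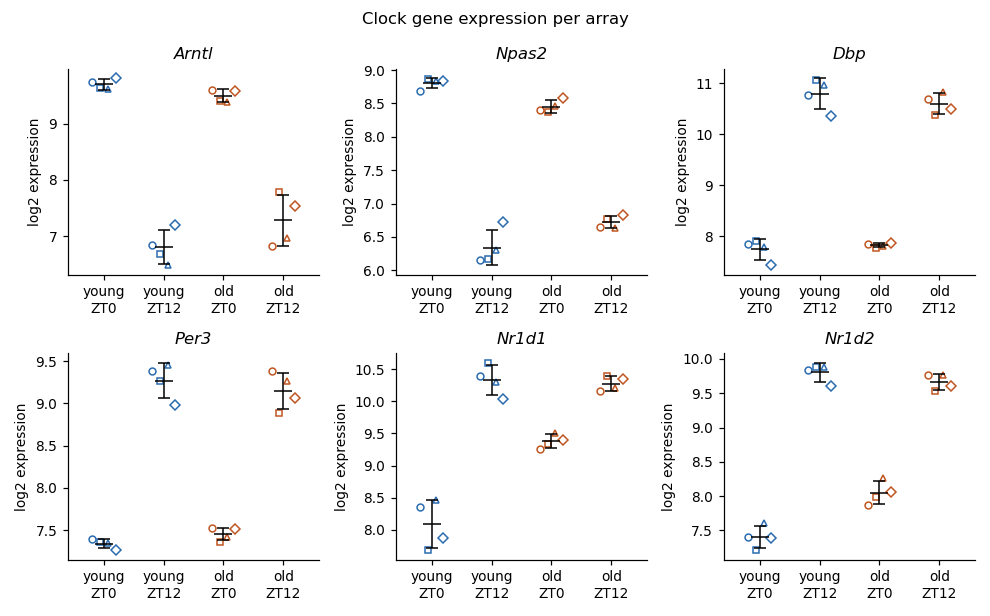
Log2 expression of 6 clock genes in each of the 16 arrays, by group; open symbols are arrays (circle, square, triangle and diamond for replicates 1 to 4), and black bars are the group mean with its SD. Arntl and Npas2 were lower and the other genes higher at ZT12 at both ages, and the old ZT0 arrays of Nr1d1 lay above every young ZT0 array.

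In young mice, all 12 tested members of the list of clock genes that peak towards evening rose, and the same 12 did when adjusted over the list alone. Of the 5 tested members of the morning list, 4 fell (Arntl, Npas2, Clock and Nfil3) and Cry1 was not called, with a log2 change of -0.13 (SE 0.13). Both lists were called by camera (adjusted p = 7.56e-35 and 1.71e-13), and both calls held with an estimated correlation (adjusted p = 0.000253 for each). The second probe set of Tef gave a change of 0.28 where the one used gave 1.31. Per2 and Rbm3 were not analysed here.

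Of 14 tested heat shock proteins and co-chaperones 9 fell in young mice, and 13 fell when adjusted over the list alone. Hsph1 fell by 1.49 (SE 0.18, adjusted p = 0.000237), Stip1 by 0.86 (SE 0.13) and Hspa8 by 0.44 (SE 0.056). Hspa1b fell by 2.12 (SE 0.47), although its near-identical paralog Hspa1a makes the split between these genes uncertain. The list's call (adjusted p = 1.11e-17) was lost with an estimated correlation (adjusted p = 0.143 with an estimated correlation). By fry, which called 4 of 37 lists in this comparison, it was called (adjusted p = 0.00197). Among these arrays, young ZT0 replicate 4 had a heat shock list median of 0.63, against 0.26 to 0.29 in the other arrays of its group.

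Among extracellular matrix genes 6 of 32 fell in young mice and none rose; adjusted over the list alone, 6 fell and 1 rose. Eln, which encodes elastin, fell by 1.37 (SE 0.13, adjusted p = 1.9e-05). Serpinh1, the collagen chaperone, and P4ha1, a collagen prolyl hydroxylase, each fell by 0.61 (SE 0.088 and 0.13). The list's call (adjusted p = 0.000371) was lost with an estimated correlation (adjusted p = 0.752 with an estimated correlation). Of 23 detoxification genes 6 rose and none fell, and adjusted over the list alone 8 rose and 1 fell. Ephx1, an epoxide hydrolase, rose by 0.42 (SE 0.065), and Alas1, the first enzyme of heme synthesis, rose by 0.37 (SE 0.058). This list's call (adjusted p = 0.000199) was also lost (adjusted p = 0.408 with an estimated correlation). By fry the detoxification list was called (adjusted p = 0.0189) and the matrix list was not (adjusted p = 0.266). The complement list (adjusted p = 0.0406) had 2 genes that rose, Cfb and C4b, and 1 that fell, Hc, and 10 that were not called; adjusted over the list alone, 5 rose and 1 fell (adjusted p = 0.539 with an estimated correlation).

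In total 492 genes were called between ZT12 and ZT0 in young mice at an adjusted p under 0.05, of which 213 rose and 279 fell, and 21 of them changed at least 2-fold. With the arrays centred on their medians the split was 240 against 194. The count was 301, 323 and 258 without young ZT0 replicates 1, 2 and 4 and 275 without young ZT12 replicate 3. It was 296 with no filter on dim probe sets, 739 with array weights and 297 with the 8 arrays of these groups alone.

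The second comparison asked the same question of old mice. Dbp was 6.86-fold higher at ZT12 (log2 change 2.78, SE 0.14, adjusted p = 2.29e-08), Per3 rose by 1.7 (SE 0.1) and Nr1d2 by 1.62 (SE 0.099). Arntl fell by 2.22 (SE 0.18), Npas2 by 1.73 (SE 0.1) and Spon2 by 2.49 (SE 0.14). The heat shock gene Hspa1b fell by 3.53 (SE 0.47) and Hspa1a fell by 3.01 (SE 0.46), again with an uncertain split between the paralogs. Zbtb16, a transcription factor induced by glucocorticoids, rose by 1.81 (SE 0.48, adjusted p = 0.0356). Cirbp, a cold-inducible RNA-binding protein, rose by 0.92 (SE 0.13, adjusted p = 0.000715), and in young mice its change was 0.36 (SE 0.13, adjusted p = 0.157). The interaction for Cirbp was not called (0.56, SE 0.18, adjusted p = 0.942); Cirbp was the only tested gene of its list, so adjusted over the list alone its p was the unadjusted 0.0076.

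In old mice 11 of 12 evening clock genes rose and Bhlhe40 was not called (0.37, SE 0.11, adjusted p = 0.0639); adjusted over the list alone, all 12 rose. Of the 5 morning genes 4 fell, on both adjustments. Both clock lists were called (adjusted p = 1.47e-23 and 1.62e-09) and stayed called with an estimated correlation (adjusted p = 0.00141 for each). All 14 tested heat shock genes fell, on both adjustments. Hsph1 fell by 2.14 (SE 0.18) and Stip1 fell by 1.22 (SE 0.13). This list was called with the preset and the estimated correlation (adjusted p = 6.6e-27 and adjusted p = 0.0371 with an estimated correlation). Of 32 extracellular matrix genes 5 fell and none rose, with Eln lower by a log2 change of -0.95 (SE 0.13) and Serpinh1 by -0.81 (SE 0.088); adjusted over the list alone, 7 fell and 1 rose. Its call (adjusted p = 0.00967) was lost (adjusted p = 0.699 with an estimated correlation). Of 23 detoxification genes 5 rose and 1, the glutathione synthesis gene Gclc, fell. Adjusted over the list alone, 10 rose and 1 fell. This list was called by the preset test (adjusted p = 0.000345) and not with an estimated correlation (adjusted p = 0.387). By fry the detoxification list was called (adjusted p = 0.0112) and the matrix list was not (adjusted p = 0.393). Of 15 alveolar type 1 cell markers 3 rose, Gprc5a, Pdpn and Lmo7, and adjusted over the list alone 3 rose and 1 fell. The list was called by the preset test (adjusted p = 0.00472), but not by fry (adjusted p = 0.0545) or with an estimated correlation (adjusted p = 0.676).

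**Figure D2:**
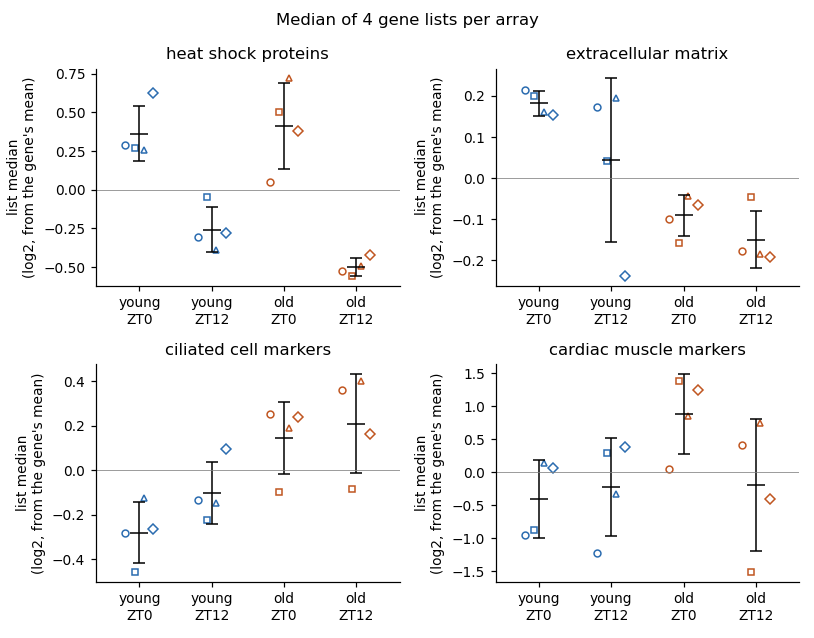
Median of 4 gene lists in each of the 16 arrays, as the log2 distance from each gene's mean over all arrays; open symbols are arrays (circle, square, triangle and diamond for replicates 1 to 4), and black bars are the group mean with its SD. The heat shock median was -0.50 at ZT12 and 0.41 at ZT0 in old mice, and the cardiac marker median ranged from -1.51 to 0.75 within the old ZT12 group.

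Cardiac muscle is present in the walls of pulmonary veins. The median of its markers was 0.89 (SD 0.6) in old ZT0 arrays and -0.19 (SD 1) in old ZT12 arrays, with -0.40 (SD 0.59) and -0.22 (SD 0.74) in young ZT0 and ZT12 arrays. Of the 17 markers Nppb alone fell between ZT0 and ZT12 in old mice, by 0.70 (SE 0.17), on both adjustments. Its old ZT12 mean (5.43) lay below the log2 5.626 used as the filter on dim genes, and old ZT0 replicate 1 (5.42) lay within the old ZT12 values (5.39 to 5.47), so the size of this change is uncertain. The list's call (adjusted p = 5.41e-06) was lost with an estimated correlation (adjusted p = 0.676 with an estimated correlation). Fat cell markers, of which 0 of 10 were called on either adjustment in old mice, had medians of 0.41 (SD 0.27) at ZT0 and -0.10 (SD 0.57) at ZT12. In old mice 917 genes were called in total, of which 547 rose and 370 fell, and 26 of them changed at least 2-fold. With the cardiac marker median as a covariate, chosen after seeing the data, 424 were called, and with the 8 arrays of these groups alone 470. The count was 596 and 495 without old ZT0 replicates 2 and 3 and 592 and 579 without old ZT12 replicates 3 and 4.

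Across genes, the changes at the 2 ages went together. Of the called genes 125 rose at both ages, against 7.46 for independent lists, 164 fell at both, against 6.61, and 0 went opposite ways. Over all 15626 genes the correlation of the log2 changes across genes was 0.536 (Spearman 0.511); genes are not independent replicates. Of the 492 genes called in young mice 475 had the same sign in old mice. The median ratio of the old to the young change depended on the genes taken: it was 0.797 over these, 1.47 over the 917 called in old mice and 0.601 over all genes. These comparisons share no arrays but share the estimate of the spread.

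**Figure D3:**
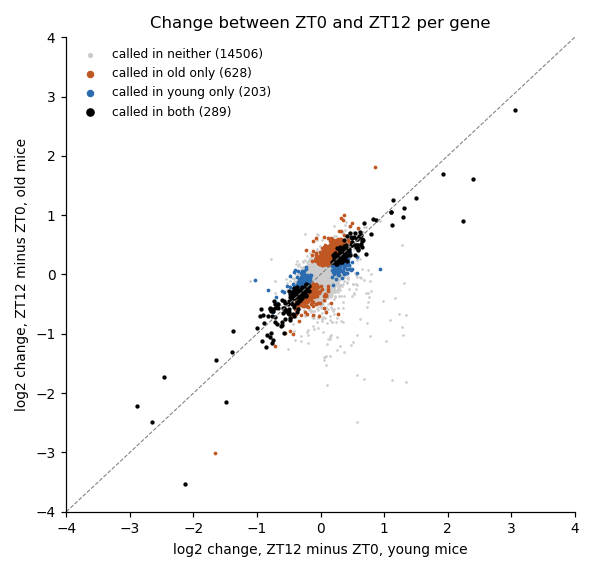
Log2 change between ZT0 and ZT12 in young mice (horizontal) and old mice (vertical), 1 point per gene over 15626 genes, with the line of equal change dashed; colours mark whether a gene was called at both ages, at 1 age or at neither. The 289 genes called at both ages lie in the lower left and upper right.

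The interaction compared the change between ZT0 and ZT12 at the 2 ages directly. The clock genes Nr1d1 and Nr1d2 had smaller changes in old mice, with differences of -1.34 (SE 0.21) and -0.78 (SE 0.14), and Npas2 and Arntl had differences of 0.74 (SE 0.14) and 0.68 (SE 0.25). Over all genes tested their adjusted p-values were 0.174, 0.247, 0.342 and 0.942. Adjusted over the list alone, the differences of Nr1d1 (adjusted p = 0.000133), Nr1d2 (0.00027), Npas2 (0.000547) and Arntl (0.0428) passed, which makes 2 of 12 evening genes and 2 of 5 morning genes. Nr1d1 was at 8.09 (SD 0.37) in young and 9.38 (SD 0.11) in old arrays at ZT0, and at 10.33 (SD 0.24) and 10.28 (SD 0.11) at ZT12.

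No gene was called in the interaction by limma over all genes tested, and 770 of the 15626 (4.93%) had an unadjusted p under 0.05. All 14 heat shock genes had a larger fall in old mice by sign, with a median difference of -0.30, and 0 were called on either adjustment. Of the 17 cardiac markers, 0 were called on either adjustment, with a median difference of -1.20. The fat cell list had a median of -0.80, with 0 of 10 called and 1, Fabp4, when adjusted over the list alone. The preset test called these 3 lists (adjusted p = 1.76e-09, 2.05e-09 and 2.55e-07). With an estimated correlation none of them was called (adjusted p = 0.357, 0.37 and 0.331 with an estimated correlation), and of the 17 lists called in all, 0 were. Of 13 complement genes 0 were called. Adjusted over the list alone, C1qa, Cfb and C1qb passed with negative differences and Hc with a positive one. The complement list was called by the preset test (adjusted p = 0.00118) and not with an estimated correlation (adjusted p = 0.254). Cxcl9, of the interferon list, and Sprr1a, of the stratified epithelium list, also passed adjusted over the list alone (adjusted p = 0.0442 and 0.000142), and neither was called over all genes (adjusted p = 0.827 and 0.247). Without young ZT0 replicate 3 the count was 1, and without young ZT12 replicate 4 it was 2.

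The age comparison at ZT0 asked what differed between old and young lungs at lights on. The 4 called genes with the largest rises were immunoglobulin transcripts, made by B cells and plasma cells. Igkv4-59 rose by 3.6 (SE 0.89, adjusted p = 0.0494), and Igkj1 was 7.85-fold higher in old mice (log2 change 2.97, SE 0.59, adjusted p = 0.0244), Igkv4-72 6.47-fold (2.69, SE 0.65) and Ighm 3.92-fold (1.97, SE 0.48). The 6 other probe sets of Ighm gave log2 changes between 0.37 and 2.4. Penk, the precursor of enkephalins, rose by 1.32 (SE 0.19), Nr1d1 by 1.29 (SE 0.15, adjusted p = 0.00106) and Il23r, a subunit of the interleukin 23 receptor, by 1.14 (SE 0.17). Sprr1a, an epithelial cornified envelope protein, fell by 1.24 (SE 0.12, adjusted p = 0.000302), Aplnr, the apelin receptor of endothelial cells, by 1.55 (SE 0.28), and Phex, an endopeptidase, by 1.38 (SE 0.26). In Igkv4-59 and Il23r the young ZT0 means (4.06 and 5.1) and in Phex the old ZT0 mean (5.33) lay below the log2 5.626 used as the filter on dim genes, so the sizes of these changes are uncertain. Nr1d2 rose by 0.64 (SE 0.099), so 2 of 12 evening clock genes rose, and 4 did when adjusted over the list alone. The other 10 were not called over all genes. Of the 5 morning genes 0 were called and 2 fell when adjusted over the list alone. The evening and morning lists were called by the preset test (adjusted p = 0.000377 and 0.0354) and by fry (adjusted p = 0.0402 and 0.0438). Neither was called with an estimated correlation (adjusted p = 0.32 for each). With the cardiac covariate the difference of Nr1d2 was 0.538 with an SE of 0.115, against 0.641 with an SE of 0.0987, and it was no longer called (adjusted p = 0.169).

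Of 18 markers of ciliated airway cells 4 rose in old mice at ZT0 (Dynlrb2, Hydin, Ccdc113 and Tekt1) and none fell, and adjusted over the list alone 16 rose and 1 fell. Dynlrb2, a dynein light chain, rose by 0.55 (SE 0.11). The second probe set of Hydin gave -0.11 where the one used gave 0.63. Of 32 matrix genes 5 fell, and 15 fell when adjusted over the list alone. Tnc, the matrix glycoprotein tenascin C, fell by 0.81 (SE 0.16), Postn by 0.52 (SE 0.1) and Eln by 0.55 (SE 0.13). Both lists were called (adjusted p = 1.17e-11 and 4.48e-11) and neither was with an estimated correlation (adjusted p = 0.32 with an estimated correlation for each). By fry, which called 8 of 37 lists in this comparison, both were called (adjusted p = 0.0402 for each). Of 20 surfactant and alveolar type 2 cell genes 3 fell, Hc, Dram1 and Muc1, and 8 did when adjusted over the list alone. This list was called by the preset test (adjusted p = 7.64e-06) and by fry (adjusted p = 0.0457), but not with an estimated correlation (adjusted p = 0.32).

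Of 13 complement genes 3 rose, Cfb by 0.48 (SE 0.073), C4b by 0.59 (SE 0.11) and C1qa by 0.32 (SE 0.074), and Hc fell; adjusted over the list alone, 4 rose and 1 fell (adjusted p = 0.32 with an estimated correlation). Of 22 T and natural killer cell markers 2 rose, the chemokine receptor Cxcr6 by 0.72 (SE 0.11) and the T cell receptor chain Cd3g by 0.60 (SE 0.12), and 4 did when adjusted over the list alone (adjusted p = 0.32 with an estimated correlation). Of 15 B and plasma cell markers Ighm alone rose, and 2 did when adjusted over the list alone (adjusted p = 0.422 with an estimated correlation). Of 17 cardiac markers 0 were called at ZT0 and 10 rose when adjusted over the list alone, with a median of 1.37 (adjusted p = 0.32 with an estimated correlation). Of 10 fat cell markers 0 were called and 5 rose when adjusted over the list alone (adjusted p = 0.32 with an estimated correlation). Their list median was -0.28 (SD 0.14) in young and 0.41 (SD 0.27) in old ZT0 arrays. The preset test called the complement, T and natural killer cell, B and plasma cell, cardiac and fat cell lists (adjusted p = 0.00209, 0.00119, 0.000213, 1.4e-07 and 1.37e-05). Of these, fry called the complement list alone (adjusted p = 0.0402).

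In total 324 genes were called at ZT0, of which 218 were higher and 106 lower in old mice, and 13 changed at least 2-fold. The split was 268 against 81 with the arrays centred on their medians and 203 against 148 with quantile normalization. The count was 5 with the cardiac marker covariate, 99 with no filter on dim probe sets, 89 over every probe set and 521 with array weights. It was 36, 39, 163 and 39 without young ZT0 replicates 1, 2, 3 and 4, 73 and 25 without old ZT0 replicates 3 and 4, 195 without old ZT12 replicate 4 and 527 without young ZT12 replicate 4.

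At ZT12 no gene was called between old and young lungs by limma, the smallest adjusted p was 0.122, and 2273 genes (14.5%) had an unadjusted p under 0.05. Without the array labelled young ZT12 replicate 4 the count was 297, of which 179 were higher and 118 lower in old mice, and with array weights it was 43. That array stood with the old arrays in genes called for age at ZT0: Phex was at 5.32 in it and between 6.78 and 6.86 in the other young ZT12 arrays, with 5.44 (SD 0.33) in the old ZT12 group. Veph1 was at 5.48 in it, against 6.21 to 6.35 in the other young arrays of that time. Over the 425 genes called for age at ZT0 in the 8 ZT0 arrays alone, it was nearer to the old than to the young ZT12 mean in 82.6%. The other young ZT12 arrays were nearer to the old mean in 9.88% to 23.5% of these genes, and the old ZT12 arrays in 46.6% to 88.9%.

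**Figure D4:**
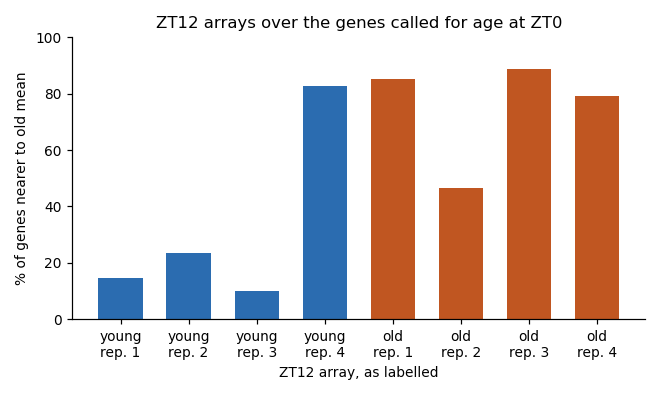
Share of the 425 genes called for age in the ZT0 arrays alone in which each ZT12 array was nearer to the mean of the old ZT12 arrays than to that of the young ones; an array was left out of its own mean, and the array labelled young ZT12 replicate 4 out of the young mean. That array is at 82.6%, and the other young arrays are at 23.5% or less.

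With all 16 arrays, the direction of the ZT0 age differences was mostly found again at ZT12. Of the 324 genes called at ZT0, 307 (94.8%) had the same sign at ZT12, and the correlation of the log2 changes across these genes was 0.871. Over all 15626 genes the share with the same sign was 66.4% and the correlation 0.509. Genes are not independent replicates. The median ratio of the ZT12 to the ZT0 change was 0.508 over the 324 genes, taken by their call at ZT0, and 0.457 over all genes. Of 32 matrix genes 0 were called at ZT12 and 11 fell when adjusted over the list alone; the collagen gene Col3a1 had a change of -0.73 (SE 0.2, adjusted p = 0.153). Of 18 ciliated cell markers 0 were called, and adjusted over the list alone 10 rose and 1, Mcidas, fell. Of 14 heat shock genes 0 were called and 6 fell when adjusted over the list alone. The preset test called these 3 lists (adjusted p = 1.93e-11, 6.41e-06 and 2.31e-07), and with an estimated correlation it called none (adjusted p = 0.592 with an estimated correlation for each). None of the 17 tested clock genes was called at ZT12 with all arrays; adjusted over the list alone, 2 of the 5 morning genes rose, Npas2 and Arntl, and 0 of the 12 evening genes passed. The morning list had a median of -0.009 and a mean of 0.109, which differ in sign. Npas2 was at 0.38 (SE 0.1, adjusted p = 0.148), and without the array labelled young ZT12 replicate 4 it was called (0.51, SE 0.069, adjusted p = 0.00201).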

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

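The tests of a wrong label, of an exchange of arrays, of a later point of the cycle, of the authors' normalization and of cardiac muscle for the clock genes and for the age calls were chosen after the results were seen. So was the averaged age difference, as well as the rule on relabelings for it and for the interaction; the bounds for cardiac muscle in the array labelled young ZT12 replicate 4 were written before its value was seen.

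In 564 checked groups of 4 arrays, 35 had 1 array far from the other 3, where chance gives 28.2; the measure is the gap to the nearest array as a share of the group's range, above Dixon's critical value for 4 samples at the 0.05 level. The array labelled young ZT12 replicate 4 had 8 of these. It was low in Phex (0.953), Veph1 (0.845) and Lyz1 (0.904) and in the medians of the evening clock (0.838) and interferon (0.833) lists. It was high in Tekt1 (0.839), Tekt4 (0.965) and the T and natural killer cell median (0.876). Young ZT12 replicate 3 was low in Nfil3 (0.851) and in the morning clock (0.902) and complement (0.863) medians, replicate 2 was high in Chordc1 (0.833) and replicate 1 was high in Sprr1a (0.878). Young ZT0 replicate 4 was high in the heat shock genes Hsph1 (0.926), Stip1 (0.872) and Chordc1 (0.908) and in the heat shock median (0.914). Young ZT0 replicate 2 was high in Eln (0.914) and Hc (0.842) and low in the B cell genes Blk (0.908), Cd22 (0.847) and Igkv4-72 (0.974), and replicate 3 was low in Tmem100 (0.902). Old ZT0 replicate 2 was low in Igkj1 (0.844), at 7.29 against 10.14 to 10.66 in the others, and in Fmo2 (0.931), Dram1 (0.865) and Sparc (0.884), and high in Cxcr6 (0.922); replicate 4 was high in Tnc (0.85). Old ZT12 replicate 3 was high in Per1 (0.968) and Il33 (0.9) and low in Pdpn (0.875) and Tpx2 (0.984), and replicate 2 was low in Hspa8 (0.873) and high in the matrix median (0.891).

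No gene was called in the interaction over all genes, and 12 passed adjusted over the list alone, with no adjustment across lists. Of these, 4 were clock genes, Nr1d1 (adjusted p = 0.000133), Nr1d2 (0.00027), Npas2 (0.000547) and Arntl (0.0428), and 4 complement genes, C1qa (0.0187), Cfb (0.0203), C1qb (0.0304) and Hc (0.0477). The others were Sprr1a (0.000142, in a list of 3 tested genes), Cirbp (0.0076, alone in its list), Fabp4 (0.0397) and Cxcl9 (0.0442). With the preset correlation 17 lists were called in the interaction, and none of them with an estimated correlation. These were the evening clock (adjusted p = 2.18e-06), morning clock (0.00787), heat shock (1.76e-09), immediate early (0.00696), T and natural killer cell (0.00846), antigen presentation (0.00203), complement (0.00118), pathogen sensing (0.025) and neutrophil (0.00787) lists. The others were the alveolar type 1 cell (0.0198), club cell (0.00846), ciliated cell (0.00203), fibroblast and mural cell (0.00787), respiratory chain (0.000118), cardiac (2.05e-09), skeletal muscle (0.0492) and fat cell (2.55e-07) lists.

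Of the 35 splits of the 8 arrays of a comparison, 1, the real one, gave as many called genes for time in young mice (492, highest other 0). The same held for time in old mice (917, highest other 1) and age at ZT0 (324, highest other 7). The counts thus went with the labelled groups. However, 1 of 35 is the smallest share these splits can give, and every other split mixes the labelled groups, so chance was not excluded. For age at ZT12 and for the interaction the real count was 0, so all 35 splits and all 100 relabelings (highest other 4) gave as many by construction, and they say nothing about chance. The ZT12 split that exchanged the array labelled young replicate 4 with old replicate 2 called 252 genes. It was picked as the highest of all the ZT12 splits, and what lies behind its count was not tested.

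The array labelled young ZT12 replicate 4 was nearer to the old than to the young mean in 82.6% of 425 age genes. This is above the lowest old array (46.6%) and the highest other young array (23.5%), which is what a wrong age label would give. In its matrix and ciliated cell medians (-0.238 and 0.098) this array also stood with the old ZT12 arrays. Its heat shock median (-0.281) did not. That value lay within the other young ZT12 arrays (-0.392 to -0.048) and above the old ones (-0.556 to -0.423). With every array at the same cardiac marker level its share was 71.5%, between 30.4% for the highest other young array and 80.5% for the lowest old arrays, so cardiac or other tissue in the piece cannot be told apart as a part of the pattern. For an exchange with old ZT12 replicate 2, that array's own share of 46.6%, between the other young and the other old arrays (79.3% or more), did not decide. Of 2 measures taken after it was seen, the share at the same cardiac level was 80.5%, and 23 of the 33 called genes named for age at ZT0 were nearer to the old mean, between the other young arrays (4 or fewer) and the other old arrays (29 or more), so an exchange stays open. A wrong label is a candidate explanation only, and a young lung that resembled the old ones was not tested.

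Nr1d1 and Nr1d2 were both higher in old mice at ZT0. With quantile normalization added, the difference of Nr1d1 was 1.27. That step acted on values already normalized, with array medians between 6.249 and 6.302. It could hardly move the difference and cannot test the authors' method, which stays open for both genes. For Nr1d1 the difference was 1.32 (adjusted p = 0.0238) with the cardiac covariate, against 1.287 without it. These values argue against cardiac muscle for Nr1d1, as far as the marker median tracks it, although Nr1d1 was taken by its call. For Nr1d2 the difference was 0.538 with the covariate, against 0.641, and was no longer called (adjusted p = 0.169). Its SE was 0.115 in place of 0.0987. Most of that difference stayed, but Nr1d2 was itself taken by its call, and the call ended through both a smaller change and a larger error. Cardiac muscle thus stays open for Nr1d2. Old mice may have been sampled at a later point of their cycle. As a share of the young time change, the age difference was 0.574 for Nr1d1 and 0.267 for Nr1d2. The median over the 15 other clock genes was 0.0791, with 12 of them towards the ZT12 level. Both terms of this share use the same young ZT0 arrays, and all 15 genes come from the same arrays, so they are not independent. The share of Cry1 (3.24) rests on a young time change that was not called. The median and the count of 12 therefore cannot decide on later sampling, which stays open. An effect of age on these genes was not tested apart from these.

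Of 17 cardiac markers 0 were called for age at ZT0, with a median difference of 1.37. Their list was called by the preset test (adjusted p = 1.4e-07) and not with an estimated correlation (adjusted p = 0.32). With the median of these markers in each array as a covariate, 5 genes were called for age at ZT0 in place of 324. The 324 genes nevertheless had a median of 0.838 of their log2 change left (quartiles 0.724 and 0.94). They were taken by their call, which favours genes with a small spread within groups. The cardiac median varied within the ZT0 groups (SD 0.59 in young and 0.6 in old). The selection thus favours a high share left, which cannot decide on cardiac muscle. The median change of the 324 genes went from 0.431 to 0.35 and their median SE from 0.0907 to 0.103, so the calls ended through both a smaller change and a larger error. Cardiac muscle as the whole or a part of the cause, and an effect of age itself, stay open.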

How the results depend on the processing

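The cardiac covariate, the left-out least correlated arrays and age averaged over both times were chosen after the data were seen; the other alternatives were planned. Counts of called genes, given for young time, old time, age at ZT0, age at ZT12 and the interaction, moved beyond 1.5 times as follows. With no filter they were 296, 99 and 1 for young time, age at ZT0 and age at ZT12; with array weights 739, 521 and 43; over every probe set 89 and 1 for age at ZT0 and ZT12; with the cardiac covariate 424 for old time and 5 for age at ZT0; without the least correlated arrays 297 for young time and 434 for age at ZT12; and with only 8 arrays 297 and 470 for young and old time. Leaving out 1 array gave 258 to 537, 495 to 1148, 25 to 527, 0 to 297 and 0 to 2. The counts moved both up and down, and the cause was not tested. Of the 13, 15, 20, 10 and 17 lists called, an estimated correlation called 2, 3, 0, 0 and 0 in number, fry 4, 5, 8, 0 and 0, and the cardiac covariate left 10 for age at ZT0 and 7 for the interaction. With that covariate, lists changed direction without being called: cardiac markers in old time (adjusted p = 0.653), age at ZT0 (0.472) and the interaction (0.663), club cell markers in age at ZT0 (0.178) and the interaction (0.825), and alveolar type 1 markers in the interaction (0.959); the covariate is the cardiac list's own median. Of the named called genes 27 of 43, 31 of 48 and 2 of 33 stayed called under every alternative for young time, old time and age at ZT0; a change of sign in a gene or list called on neither side was not counted. With the replicate block 481, 943, 461, 0 and 0 genes were called. Of 24 same-numbered pairs 11 had a correlation of deviations over 0.1, across genes, and 7 matched best with their own number. This shows no clear pairing by number, and a factor shared by number was not excluded. Without detection calls, what signal over background limits was not assessed.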

Other observations

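The age difference averaged over both times and the genes named from the comparison without 1 array were chosen after the data were seen. Averaged over both times, 1146 genes differed between old and young lungs, 734 higher and 412 lower in old mice, and 306 of them were also called at ZT0. Bbox1, the last enzyme of carnitine synthesis, rose by 0.98 (SE 0.14, adjusted p = 0.00294), Il7r, the interleukin 7 receptor, by 0.77 (SE 0.1), and Jchain, which joins immunoglobulin M and A, by 1.97 (SE 0.51, adjusted p = 0.032). Of 18 ciliated cell markers 14 rose and 1 fell, of 32 matrix genes 14 fell, and of 20 surfactant and alveolar type 2 cell genes 5 fell and 1 rose. The preset test called these lists (adjusted p = 1.68e-10, 5.75e-14 and 4.26e-06), and with an estimated correlation none was called (adjusted p = 0.557 for each). Of 100 relabelings 1, the real one, gave as many genes, and the highest other gave 34. This is the smallest share that 100 relabelings can give, and the others mix the labelled ages, so chance was not excluded. The count was 224 with the cardiac covariate. It was 712 and 641 without young ZT0 replicates 1 and 2, 685 and 613 without young ZT12 replicates 2 and 3, 606 without old ZT0 replicate 4 and 723 without old ZT12 replicate 3.

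Without the array labelled young ZT12 replicate 4, 60 of the 179 genes higher in old mice at ZT12 were also higher at ZT0, against 2.5 for independent lists, 24 of the 118 lower genes were also lower, against 0.8, and 0 went opposite ways. Among them were Phex (-1.38, SE 0.14), whose old ZT12 mean (5.44) lay below the log2 5.626 used as the filter on dim genes, and Bbox1 (1.18, SE 0.14). The array was singled out after its values were seen, for its likeness to old arrays in genes called for age at ZT0. Leaving it out thus favours this overlap by itself, and the values for independent lists are no fair reference. Markers of platelets had group means of the list median of -0.68 (SD 0.36), -0.07 (SD 0.58), 0.06 (SD 0.81) and 0.74 (SD 0.43) in young ZT0, young ZT12, old ZT0 and old ZT12 arrays. Of 11 markers 0 were called for time or for age at either time, and 1 rose with age averaged over both times. The preset test called the list for young time, old time, age at ZT0 and age at ZT12 (adjusted p = 0.00401, 0.00472, 0.000184 and 4.44e-05). None of these calls held with an estimated correlation (adjusted p = 0.752, 0.699, 0.422 and 0.592). Cdkn1a, a cell cycle inhibitor, fell from ZT0 to ZT12 by 0.90 (SE 0.21) in young and by 0.81 (SE 0.21) in old mice, and Igfbp3 by 0.74 and 0.62 (SE 0.14 each). The senescence list that holds them was called in old mice (adjusted p = 0.00967), and not with an estimated correlation (adjusted p = 0.216 with an estimated correlation). There 2 of its 19 genes fell, on both adjustments. In young mice the list was not called by the preset test (adjusted p = 0.0556), and 3 of its genes fell, or 4 when adjusted over the list alone. By fry it was called in old mice (adjusted p = 0.0331) and not in young mice (adjusted p = 0.0697).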
